A study of Arabidopsis thaliana with 12 samples.

How the data were processed

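RNA was measured in whole Arabidopsis thaliana plants of 4 genotypes with 3 replicates each, 12 libraries in all: wild type (accession Col-0), djc31, djc62 and the double mutant djc31 djc62. DJC31 and DJC62 are co-chaperones that carry tetratricopeptide repeats and a J domain. Per the labels' protocols, plants grew on soil to the 4-leaf stage under 16 h light of 100 µmol photons per square metre and second at 21 °C and 8 h dark at 16 °C, total RNA was taken with Trizol, and libraries were made with an Illumina TruSeq kit. The hour of harvest is not given in the sources used here. The labels do not say whether replicates came from separate sowings, so p-values measure the spread between these samples, which may be technical in part.

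Per the submitters' processing notes, the authors used Trimmomatic, FastQC and featureCounts with the build TAIR10. Versions, the aligner, the strand setting and the treatment of reads that match several places are not given in the sources used here. Reads of overlapping or antisense genes, and of near-identical copies such as LHCB1 or RBCS genes, may therefore be split or shared in an unknown way. The deposited table holds 1 normalised signal per locus and library for 36917 loci; the name of its sheet, per the file headers, names DESeq2. Each deposited value is a whole number of reads divided by 1 factor per library. Dividing by the smallest step of each library gave whole reads for 100% of values, within a tolerance of 0.01. The recovered totals ran from 13.6 M reads (djc31 replicate 2) to 31.08 M (wild type replicate 2), with a median of 25.795 M, and the factors from 0.4655 to 1.3439. A locus without reads allows up to 3 reads, which is 0.0965 to 0.221 CPM (counts scaled to library size) depending on the library. Such floors cover counting error only.

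The test fixed before the data were examined was edgeR's quasi-likelihood test on raw counts. Because the deposited values were normalised, the main test became limma with a mean-variance trend on log2(value + 1), as the plan laid down for that case. It was fitted to all 12 libraries with 1 mean per genotype and no covariate, which leaves 8 residual degrees of freedom. Loci with a value of at least 10 in at least 3 libraries were tested, 19975 in all, and 16942 were removed. P-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. Where a genotype had no reads, the fold is a bound against 3 reads over that genotype's libraries. The edgeR test on the recovered reads was added after seeing the data and called 5424, 5493, 6017, 6230, 4191 and 6279 genes in the 6 comparisons, in the order of the report.

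The comparisons were each mutant against wild type, the double mutant against each single mutant, and the non-additive contrast, which is the change of the double mutant minus the sum of both single-mutant changes. Named genes followed a rule fixed before the data were examined. It takes DJC31 and DJC62, the 10 largest rises and 10 largest falls against wild type among genes past the threshold whose libraries do not overlap and whose mean CPM is at least 5 in the higher genotype, and up to 4 members per gene list with the lowest adjusted p. For the double against single mutants it takes the 5 largest rises and 5 largest falls. For the non-additive contrast only the adjusted p and the CPM minimum were used, because non-overlap is not defined for 4 genotypes. Where no member of a list passed, the 2 of highest mean CPM were taken. Clock genes such as CCA1, LUX, PRR3, TOC1 and GI, and the damage and low-copper genes, were named outside this rule, for the tests of the closing parts. The result of 1 gene is not reported.

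Gene lists, 22 with 458 loci in all, were written before the data were examined: heat-inducible chaperones and heat shock factors, constitutive HSP70, HSP90 and their co-chaperones, endoplasmic reticulum protein folding, abscisic acid and dehydration response, cold response, oxidative stress, salicylic acid and pathogen defence, jasmonate and wounding, nucleus-encoded photosynthesis proteins, circadian clock, flowering time and floral identity, senescence, auxin, flavonoid synthesis, glucosinolate synthesis, hypoxia, iron, phosphate starvation, cell division, and root, guard cell and vascular markers. Some genes are in more than 1 list, such as ADH1 and ZAT12. Lists were tested with camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry. The estimated setting also uses the 8 residual degrees of freedom, so calls can be lost even at a low correlation. The estimate was 0.8 for photosynthesis genes and 0.02 for cell division genes. For heat-inducible genes it was 0.01, equal to the preset, yet their camera adjusted p in djc62 went from 0.0227 to 0.258. Camera asks whether a list's genes differ from all other genes; fry asks whether they move, on balance, 1 way, and does not compare them with other genes.

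Alternatives fixed beforehand were other scalings (DESeq2 size factors, upper quartile), DESeq2, limma-voom, other filters, fits with only the compared genotypes, a replicate block, removal of organellar and rRNA genes, robust fits, a fold threshold, other pseudocounts, and leaving out each library. Alternatives chosen after seeing the data were edgeR on recovered reads, TMM scaling in limma, fits without wild-type libraries, and leaving out loci near those silent in wild type. The limma test was tested on simulated data for the double mutant against wild type, with 19674 genes tested. It recovered 39.1% of 23 genes changed 1.5-fold, 75.3% of 73 changed 2-fold and 95.8% of 71 changed 4-fold, with 6 false calls among 143. The simulated spread was assumed and not estimated from these libraries, and far fewer genes were changed than were called in the data.

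Gene names came from a reference table of the assembly TAIR10.1, in which 36632 of the 36917 loci were matched; it was used for names only. No coordinates, exons or UTRs are reported, and chromosomes are read from the locus identifiers. Software was R 4.3.3 with limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1.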

Results

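The transcriptomes of wild-type Arabidopsis plants (Col-0) were compared with those of djc31, djc62 and djc31 djc62 plants at the 4-leaf stage, with 3 libraries per genotype. The series concerns the part that the co-chaperones DJC31 and DJC62 play in the response to abiotic stress; the plants were grown without a stress treatment named in the labels. Libraries held 13.6 to 31.08 M reads counted in genes, and 20704 to 23065 loci had reads in a library. Values are normalised read counts given as mean ± SD (n = 3), and adjusted p-values are from limma with Benjamini-Hochberg adjustment unless another test is named. No replicate pair differed by less than sampling noise.

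Both target genes were lower in their mutants. DJC31 (AT5G12430, chromosome 5) had 726.7 ± 49.3 in wild type, 115 ± 30.8 in djc31 and 47.5 ± 7.79 in the double mutant, so that 15.8% and 6.54% of the wild-type level were left (log2 change -2.69 ± 0.19 SE, adjusted p = 1.94e-08, and -3.92 ± 0.19 SE, adjusted p = 1.25e-10). DJC62 (AT2G41520, chromosome 2) had 516.2 ± 76.1 in wild type, 161.1 ± 50 in djc62 and 75.7 ± 17.6 in the double mutant, or 31.2% and 14.7% of wild type (log2 change -1.72 ± 0.25 SE, adjusted p = 5.26e-05, and -2.77 ± 0.25 SE, adjusted p = 3.15e-07). Each target was lower in the double mutant than in its own single mutant (adjusted p = 0.000207 for DJC31 and 0.00574 for DJC62). The sites of the mutations are not reported here, and reads outside an insertion may remain. The levels left therefore check the labels only in part and do not measure intact transcript. The other gene of the pair did not pass the test in either single mutant, with DJC62 at 412.8 ± 93.5 in djc31 (adjusted p = 0.336) and DJC31 at 878.7 ± 63.9 in djc62 (adjusted p = 0.329).

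**Figure D1:**
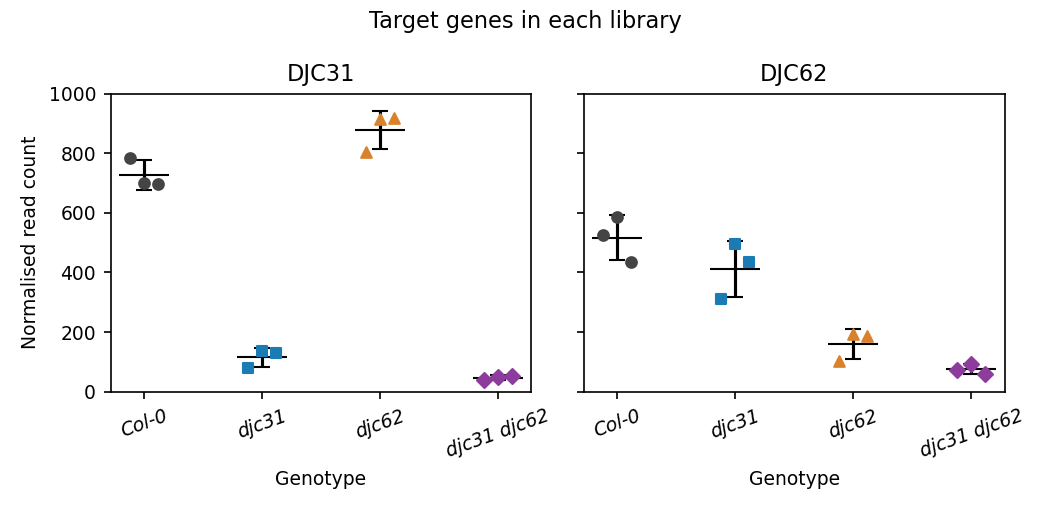
Normalised read counts (vertical axis, from 0) of DJC31 and DJC62 in each of the 12 libraries by genotype; points are libraries, and bars are mean ± SD. DJC31 fell from 726.7 in wild type to 115 in djc31 and 47.5 in the double mutant, and DJC62 from 516.2 to 161.1 in djc62 and 75.7 in the double mutant.

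Wild type stood apart from all 3 mutants on the leading principal component (35.7% of variance), with scores of -81.8 to -90.9 against 14.1 to 41.7. The double mutant stood apart from the rest on the next component (21.9%), with scores of -58.1 to -68.7. Correlations between wild-type libraries were 0.971 to 0.978 across genes, and those between wild-type and mutant libraries 0.91 to 0.934. They were 0.974 to 0.983 within djc62 and 0.983 to 0.986 within the double mutant. Within djc31 they were 0.955 to 0.966, and between djc31 and djc62 libraries 0.953 to 0.97. By this measure djc31 libraries were about as close to djc62 libraries as to each other. Genes are not independent replicates.

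**Figure D2:**
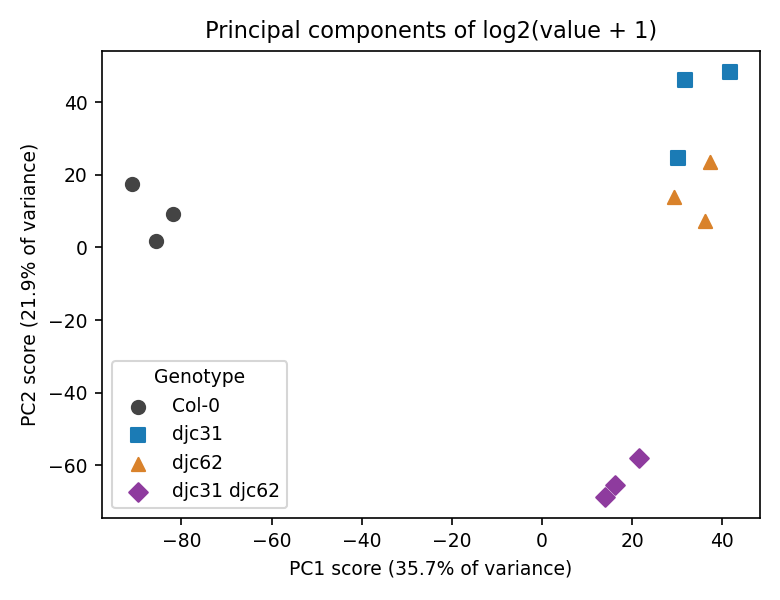
Scores of the 12 libraries on the leading principal components of log2(value + 1), with each axis labelled by its share of variance; a point is a library and its colour and shape give the genotype. The wild-type libraries lie between -81.8 and -90.9 on the horizontal axis and the mutant libraries between 14.1 and 41.7.

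Part of this separation was of an on/off kind. At 34 loci, wild type had at most 3 reads over its 3 libraries while each of the 9 mutant libraries had a value of at least 50; these were 17 protein-coding genes, 9 transposable element genes and other loci. Another 3 loci had reads in wild type but next to none in the mutants. No locus was silent in this way in djc31, djc62 or the double mutant alone. Of the 34 loci, 16 lay on chromosome 3 and 10 on chromosome 1, where 6.9 and 8.9 were due by chance. AT3G47250 had 0 reads in wild type and a mean of 1596 in djc31, 2095 in djc62 and 1726 in the double mutant, at least 1640-fold, 2160-fold and 1780-fold higher.

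**Figure D3:**
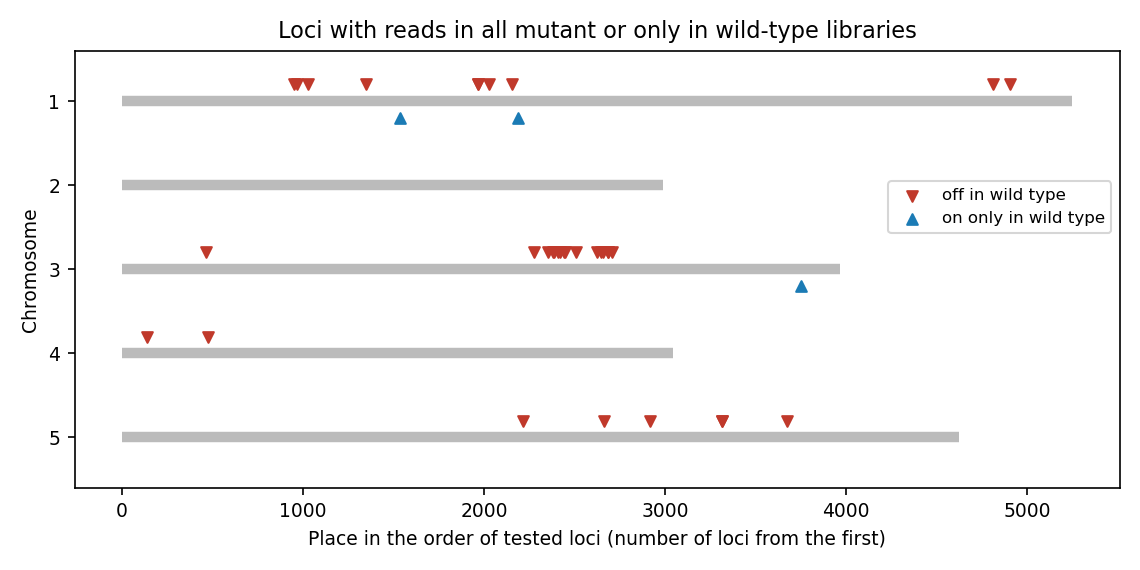
Place of the loci with reads in only wild type or in only the mutants along each chromosome, as the rank among tested loci in the order of locus identifiers (horizontal axis). Down-pointing marks are the 34 loci silent in wild type, 16 of them on chromosome 3, and up-pointing marks the 3 loci with reads in wild type.

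Clock genes also differed between wild type and the mutants. Most of the 8 dawn genes of the clock list were lower in the mutants. LHY fell from 3984 ± 298 in wild type to 1178 ± 84.7 in djc31, 2399 ± 261 in djc62 and 1705 ± 234 in the double mutant (adjusted p = 7.5e-09, 0.000178 and 8.5e-07). CCA1, RVE8, RVE1, CDF1 and LNK2 fell in all 3 mutants as well, while LNK1 fell in both single mutants only and RVE4 in the double mutant only. Of 6 evening genes, 3 rose in all 3 mutants: PRR5 rose from 6.56 ± 4.48 to 112.7 ± 34.5, 96.5 ± 20.3 and 25.7 ± 14.1, TOC1 from 254.4 ± 26.7 to 406.3 ± 41.1, 479.3 ± 75.1 and 406.4 ± 14.3, and ELF3 rose as well. LUX rose in both single mutants and did not pass in the double mutant (adjusted p = 0.36). PRR3 had lower means in all 3 mutants and fell in djc62 (log2 change -2.62, adjusted p = 0.0141). GI did not pass the test in any mutant (354.6 ± 72.6 in wild type and 439.1 ± 162, 393.6 ± 85.2 and 370.7 ± 56.1 in the mutants). The clock list as a whole, with members going both ways, did not pass in any comparison. The separation of wild type and the clock differences go with every comparison against wild type that follows.

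In djc31 against wild type, most genes of flavonoid and anthocyanin synthesis fell, some light-harvesting genes rose, and genes of the abscisic acid response were on balance lower. Of 20 flavonoid genes tested, 0 rose and 15 fell (0 and 16 adjusted over the list alone), among them PAP1, a regulator of anthocyanin synthesis (127.5 ± 50.5 to 15.5 ± 4.26, 7.63-fold lower), and TT7 (318.9 ± 8.09 to 106 ± 6.51). The list was lower than other genes (camera adjusted p = 1.29e-07, adjusted p = 0.342 with an estimated correlation). Of 43 abscisic acid and dehydration genes, 7 rose and 17 fell (8 and 19 adjusted over the list alone, camera adjusted p = 0.00691, and adjusted p = 0.342 with an estimated correlation). These included CYP707A3, which breaks down abscisic acid (1289 ± 649 to 159.5 ± 3.31), the phosphatases AHG3 (3454 ± 373 to 1159 ± 126) and HAB1 (1232 ± 27.8 to 462.3 ± 85.1), and P5CS1, of proline synthesis (3824 ± 443 to 1075 ± 326). Of 47 photosynthesis genes, 11 rose and 0 fell (11 and 0 adjusted over the list alone, camera adjusted p = 0.000254, adjusted p = 0.815 with an estimated correlation, and fry adjusted p = 0.087); LHCB1.4 rose from 114600 ± 7010 to 261000 ± 55700.

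Other genes also changed in djc31. DIN6, an asparagine synthetase induced in darkness, rose from 76.9 ± 11 to 4114 ± 579 (52.8-fold, adjusted p = 1.32e-14), and the RNA-binding protein gene GRP7, of the clock list, from 933.8 ± 19.9 to 6669 ± 770. By its locus identifier, DIN6 lies near HSD3 and AT3G47250, which are among the loci silent in wild type. The sulfur-deficiency gene LSU1 fell from 145.8 ± 54.5 to 3.64 ± 3.37. The 10 largest rises were AT3G47250, HSD2, AT1G23960, AT3G05945, AT5G51620, AT3G47675, AT1G11280, AT3G43690, AT3G42806 and AT3G43740, and all but HSD2 were among the 34 loci silent in wild type; HSD2 had 2.22 ± 2.32 in wild type and 3588 ± 419 in djc31. AT3G60950 and AT1G27570 were at least 117-fold and 112-fold lower in djc31, where they had 0 reads. Of the heat-inducible chaperones and heat shock factors, 2 rose and 8 fell of 24 tested. The list did not pass (camera adjusted p = 0.0791). HSP70-4 fell from 227.2 ± 29.9 to 48 ± 10.2. Jasmonate genes (12 rose and 4 fell of 23), glucosinolate genes (1 and 8 of 18) and defence genes (7 and 4 of 21) did not pass as lists either. Their camera adjusted p was 0.0791, 0.0791 and 0.615. In all, 5489 of 19975 genes changed, 2655 upward and 2834 downward.

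In djc62 against wild type, most of the tested jasmonate, glucosinolate and pathogen defence genes rose. Of 23 jasmonate and wounding genes, 16 rose and 2 fell (16 and 2 adjusted over the list alone, camera adjusted p = 2.35e-09, and adjusted p = 0.258 with an estimated correlation). The jasmonate synthesis genes AOC1 (892.9 ± 84.6 to 6847 ± 949, 7.63-fold) and OPR3 (1476 ± 188 to 8308 ± 1520, 5.6-fold) were among them. Of 18 glucosinolate synthesis genes, 11 rose and 2 fell (11 and 2 adjusted over the list alone, camera adjusted p = 6.14e-05, and adjusted p = 0.324 with an estimated correlation), with MAM3 at 229.4 ± 16.2 in wild type and 862 ± 158 in djc62. Of 21 salicylic acid and defence genes, 13 rose and 2 fell (15 and 3 adjusted over the list alone, camera adjusted p = 0.00125, and adjusted p = 0.519 with an estimated correlation), with ACD6 at 746.9 ± 113 and 3395 ± 756 and PR2 at 56.9 ± 21.2 and 612.7 ± 384.

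Flavonoid genes were lower in djc62 too (1 rose and 9 fell of 20, 1 and 11 adjusted over the list alone, camera adjusted p = 0.00159, and adjusted p = 0.519 with an estimated correlation). Photosynthesis genes were lower (0 rose and 7 fell of 47, 0 and 6 adjusted over the list alone, camera adjusted p = 0.00125, adjusted p = 0.726 with an estimated correlation, and fry adjusted p = 0.139), such as PSAG, from 14890 ± 2470 to 9597 ± 1540. Heat-inducible genes were lower as well (0 rose and 7 fell of 24, 0 and 8 adjusted over the list alone, camera adjusted p = 0.0227, adjusted p = 0.258 with an estimated correlation, and 0.0557 with no filter on low values), such as HSP101, from 253.1 ± 20.8 to 148.7 ± 22.4. Flowering and floral identity genes were lower (1 rose and 5 fell of 18, 1 and 5 adjusted over the list alone, camera adjusted p = 0.0264, adjusted p = 0.301 with an estimated correlation), but not without wild type replicate 2 (0.113) or without loci near those silent in wild type (0.0775); the floral repressor SVP fell from 3140 ± 399 to 1714 ± 82.4. Of 43 abscisic acid genes, 10 rose and 19 fell in djc62 (median log2 change -0.55), but the list did not pass (camera adjusted p = 0.081). DIN6 rose to 3221 ± 364 (41.4-fold). In all, 5326 genes changed, 2727 upward and 2599 downward.

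In the double mutant against wild type, most photosynthesis genes fell and most glucosinolate and hypoxia genes rose, while auxin and cell division genes were on balance higher. Of 47 photosynthesis genes, 0 rose and 31 fell (0 and 38 adjusted over the list alone, camera adjusted p = 6.42e-11, and adjusted p = 0.481 with an estimated correlation), such as RBCS1B, a small subunit of Rubisco (41730 ± 5310 to 18950 ± 2340). Of 18 glucosinolate genes, 15 rose and 1 fell (15 and 1 adjusted over the list alone, camera adjusted p = 5.38e-08, and adjusted p = 0.193 with an estimated correlation). Of 12 hypoxia genes, 8 rose and 1 fell (8 and 1 adjusted over the list alone, camera adjusted p = 0.000418, and adjusted p = 0.135 with an estimated correlation), with PCO1 at 40.8 ± 10.5 and 155.1 ± 15.8 and ADH1 at 42.3 ± 0.518 and 133.8 ± 20.1. Of 15 auxin genes, 7 rose and 0 fell (7 and 0 adjusted over the list alone, camera adjusted p = 0.00647, and adjusted p = 0.306 with an estimated correlation), with GH3.5 at 275 ± 11.6 and 796.7 ± 65.5. Of 15 cell division genes, 7 rose and 1 fell (8 and 1 adjusted over the list alone, camera adjusted p = 0.0159, and adjusted p = 0.193 with an estimated correlation), with CYCB1-1 at 109.2 ± 35.4 and 256.2 ± 5.56.

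Oxidative stress genes were lower in the double mutant (5 rose and 12 fell of 23, 5 and 13 adjusted over the list alone, camera adjusted p = 0.0343, and adjusted p = 0.481 with an estimated correlation). The copper/zinc superoxide dismutase gene CSD2 fell from 26480 ± 3110 to 5016 ± 567 (5.28-fold, adjusted p = 2.68e-10), with 20200 ± 2910 in djc31 and 15880 ± 645 in djc62, and CCS, its copper chaperone, from 4222 ± 134 to 1280 ± 167 (3.31-fold). CAT3, a catalase, rose from 14110 ± 496 to 35200 ± 1400. Abscisic acid genes (2 rose and 12 fell of 43, 3 and 14 adjusted over the list alone, camera adjusted p = 0.0343) and cold response genes (1 rose and 6 fell of 13, 2 and 6 adjusted over the list alone, camera adjusted p = 0.0421) were lower. Jasmonate genes were higher (12 rose and 5 fell of 23, 12 and 5 adjusted over the list alone, camera adjusted p = 0.0343). With an estimated correlation the adjusted p was 0.396 for the abscisic acid list and 0.481 for the cold and jasmonate lists.

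These 4 lists lay near the threshold. Without wild type replicate 3 the adjusted p was 0.0739 for the abscisic acid list, 0.119 for the cold list and 0.0955 for the oxidative list. Without loci near those silent in wild type it was 0.0626, 0.149 and 0.0717. The jasmonate list gave 0.068 without wild type replicate 2 and 0.0907 without double mutant replicate 1. The abscisic acid list gave 0.0524 without double mutant replicate 3. The cold list gave 0.0516 without djc62 replicate 1, 0.051 without djc62 replicate 3, 0.0738 without double mutant replicate 2 and 0.103 with no filter on low values. In all, 5839 genes changed, 2748 upward and 3091 downward, of which 1132 and 744 changed over 2-fold.

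**Figure D4:**
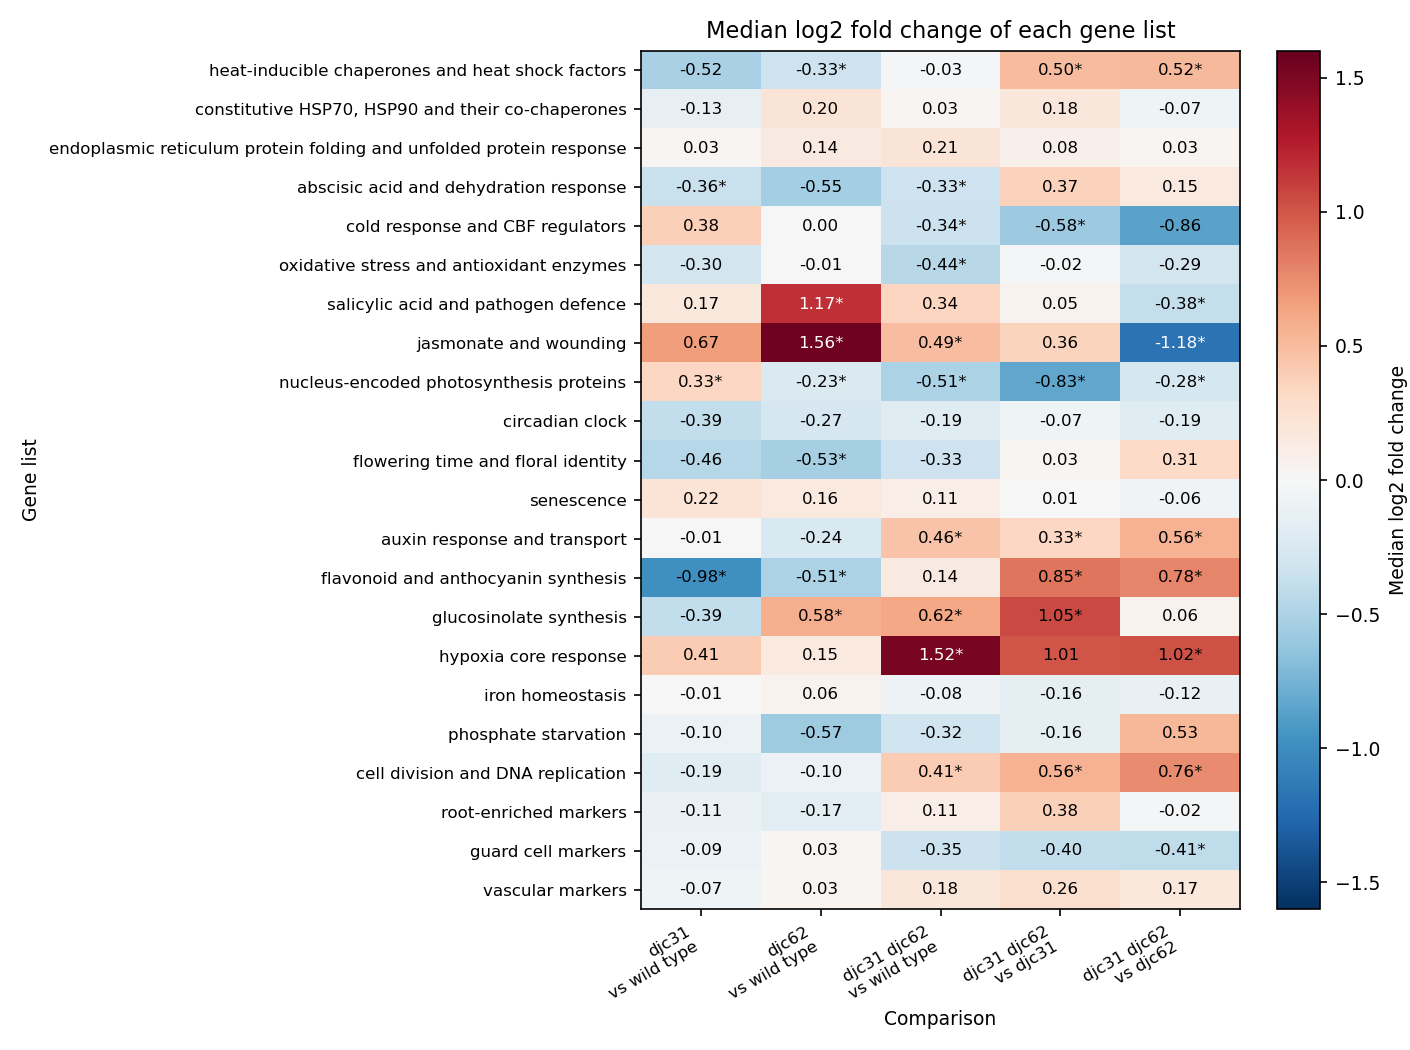
Median log2 fold change of the tested members of each of the 22 gene lists (rows) in 5 comparisons (columns); colour and number give the median, and an asterisk marks a camera adjusted p under 0.05 with the preset correlation. Photosynthesis genes have medians of -0.51 against wild type and -0.83 against djc31 in the double mutant, and jasmonate genes 1.56 in djc62 against wild type; with an estimated correlation only the cell division list of the double mutant against djc62 passed.

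Against djc31, most photosynthesis transcripts were lower in the double mutant, and most glucosinolate, flavonoid and cell division transcripts were higher. Of 47 photosynthesis genes, 0 rose and 45 fell (0 and 47 adjusted over the list alone, camera adjusted p = 5.39e-22, and adjusted p = 0.268 with an estimated correlation). Of 18 glucosinolate genes, 16 rose and 0 fell (17 and 0 adjusted over the list alone, camera adjusted p = 2.28e-13, and adjusted p = 0.0823 with an estimated correlation). Of 20 flavonoid genes, 14 rose and 0 fell (17 and 0 adjusted over the list alone, camera adjusted p = 2.63e-09, and adjusted p = 0.193 with an estimated correlation). Of 15 cell division genes, 10 rose and 0 fell (12 and 0 adjusted over the list alone, camera adjusted p = 5.66e-05, and adjusted p = 0.0677 with an estimated correlation). Heat-inducible genes were higher (8 rose and 2 fell of 24, 9 and 2 adjusted over the list alone, camera adjusted p = 0.023, adjusted p = 0.188 with an estimated correlation), but not without djc31 replicate 3 (0.0878) or without loci near those silent in wild type (0.0848). Auxin genes were higher (4 rose and 0 fell of 15, 4 and 0 adjusted over the list alone, camera adjusted p = 0.0174, and adjusted p = 0.268 with an estimated correlation), but not without djc31 replicate 2 (0.0944). Cold genes were lower (2 rose and 7 fell of 13, 2 and 7 adjusted over the list alone, camera adjusted p = 0.0174, and adjusted p = 0.423 with an estimated correlation).

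Against djc62, the double mutant had mostly lower jasmonate transcripts and, on balance, higher auxin, cell division, flavonoid, heat and hypoxia transcripts. Of 23 jasmonate genes, 0 rose and 15 fell (1 and 17 adjusted over the list alone, camera adjusted p = 3.66e-10, and adjusted p = 0.0767 with an estimated correlation). Of 15 cell division genes, 8 rose and 1 fell (9 and 1 adjusted over the list alone, camera adjusted p = 7.06e-06); this was the only list call of the 5 pairwise comparisons to hold with an estimated correlation (adjusted p = 0.0365). Other lists were on balance higher by camera, although many members did not pass: auxin (7 rose and 0 fell of 15, 8 and 0 adjusted over the list alone, adjusted p = 6.42e-06), flavonoid (11 and 2 of 20, 11 and 2 adjusted over the list alone, 2.82e-05), heat (7 and 0 of 24, 8 and 1 adjusted over the list alone, 0.0023) and hypoxia genes (6 and 1 of 12, 7 and 1 adjusted over the list alone, 0.00247). With an estimated correlation their adjusted p was 0.064, 0.324, 0.064 and 0.0767. Photosynthesis genes were lower (0 rose and 4 fell of 47, 0 and 1 adjusted over the list alone, 3.94e-05, adjusted p = 0.587 with an estimated correlation, and fry adjusted p = 0.111). Defence genes were lower (0 rose and 5 fell of 21, 1 and 6 adjusted over the list alone, 0.0146, adjusted p = 0.587 with an estimated correlation, and fry adjusted p = 0.111), but not without djc62 replicate 1 (0.183) or without loci near those silent in wild type (0.0567). Guard cell markers were lower (0 rose and 2 fell of 6, 0 and 3 adjusted over the list alone, 0.0132, and adjusted p = 0.133 with an estimated correlation), but not without loci near those silent in wild type (0.229).

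Several genes were low in the other genotypes and higher in the double mutant. HA9, a plasma membrane proton pump gene, had 139.3 ± 17.6 in the double mutant and 3.63 ± 3.9, 0.885 ± 1.53 and 0.513 ± 0.889 in wild type, djc31 and djc62. The transcription factor gene NAC044 had 197.2 ± 20.4 against 11.9 ± 9.23, 3.78 ± 4 and 16.5 ± 8.08, and AHP4, of cytokinin signalling, 180.4 ± 15.5 against 14.3 ± 11.7, 8.83 ± 3.85 and 4.15 ± 3.07. Other genes were higher in the single mutants than in wild type or the double mutant, such as PYL6, an abscisic acid receptor gene (597.9 ± 83.2 in djc31 and 483.4 ± 111 in djc62 against 45 ± 18.4 in the double mutant and 36.2 ± 18.9 in wild type). The double mutant differed from djc31 at 6255 genes (3057 higher, 3198 lower) and from djc62 at 3942 (1874 higher, 2068 lower). Among changes over 2-fold more genes were higher, 1160 against 522 lower for djc31 and 821 against 449 for djc62. In all, 1252 genes were above and 1257 below both single mutants. Without double mutant replicate 2 the count against djc31 was 4073, and without double mutant replicates 1 and 2 in turn the count against djc62 was 2375 and 2402. Upper-quartile scaling moved the share of higher calls against djc62 from 47.5% to 61.7%.

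**Figure D5:**
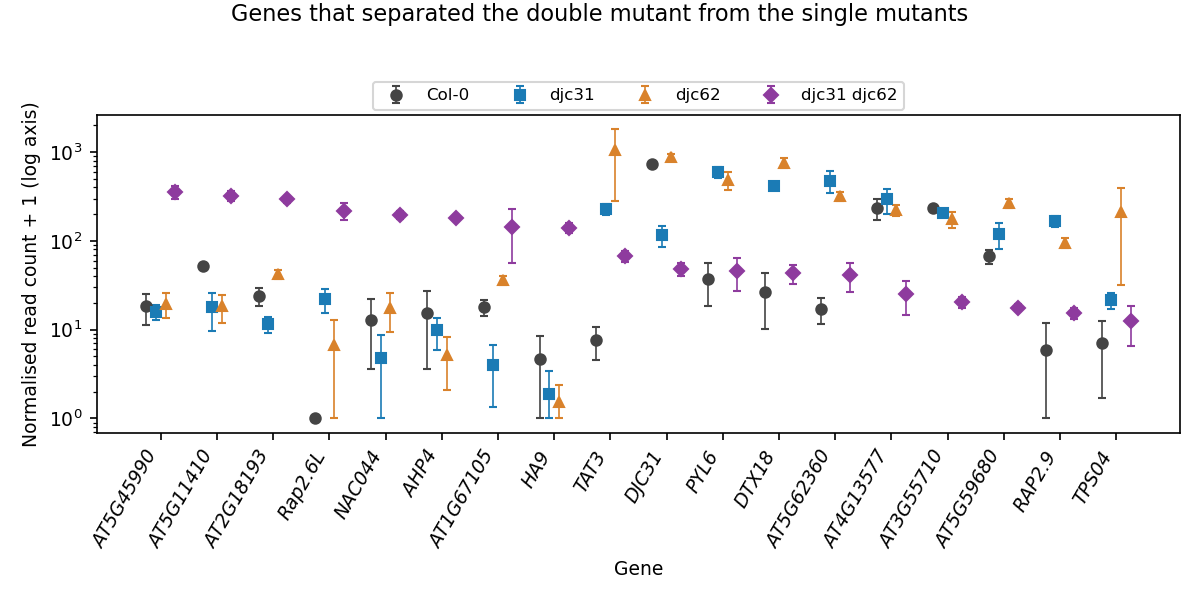
Normalised read count + 1 (log axis, mean ± SD of 3 libraries) of the genes with the largest differences between the double mutant and a single mutant, by genotype; error bars are cut at a count of 0. HA9 stands at 139.3 in the double mutant and at most 3.63 in the other genotypes, and PYL6 at 45 in the double mutant and 597.9 in djc31.

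The change in the double mutant differed from the sum of both single-mutant changes at 6236 genes (3158 above, 3078 below). This contrast contains the wild-type level, so a gene at which wild type differs alike from all 3 mutants also counts as non-additive. Of 1917 genes that changed in the same direction in all 3 mutants (942 up, 975 down), 1492 were non-additive, and at 1835 non-additive genes the double mutant differed from neither single mutant. LSU1, at 145.8 ± 54.5 in wild type, 3.64 ± 3.37 in djc31, 2.67 ± 2.39 in djc62 and 53.9 ± 19.2 in the double mutant, was the largest positive case (log2 9.52 ± 1.04 SE, adjusted p = 2.94e-06).

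The changes of djc31 and djc62 against the shared wild type were correlated across genes (Pearson r = 0.82, Spearman rho = 0.65). Unchanged groups simulated with a shared, also simulated, control group gave r = 0.5, a value that such sharing gives by construction. The covariance was 0.67, against 0.054 simulated. Both mutants rose at 1554 genes and fell at 1598, where independent lists would share 362 and 369, and 35 genes went opposite ways. For djc31 and the double mutant r was 0.65 (0.51 simulated) and the covariance 0.535 (0.054 simulated). Their rank correlation, 0.43, and share of genes with the same sign, 63.6%, lay below the simulated 0.46 and 66.7%. For djc62 and the double mutant r was 0.71 (0.5 simulated), rho 0.57 (0.46 simulated) and the covariance 0.577 (0.054 simulated). The simulated values already hold the measured spread of the shared controls. A wild-type level apart from all 3 mutants would still add to the excess. The 3 wild-type libraries were not split, since they give no parts of 2 libraries each. The effect of djc31 in wild type and its effect in the djc62 background were negatively correlated (r = -0.217, rho = -0.229), as were those of djc62 (r = -0.138, rho = -0.097).

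Other lists did not pass camera in the comparisons against wild type. Medians in djc31, djc62 and the double mutant were -0.13, 0.20 and 0.03 for constitutive HSP70 and HSP90 chaperones, 0.03, 0.14 and 0.21 for endoplasmic reticulum folding, 0.22, 0.16 and 0.11 for senescence, and -0.10, -0.57 and -0.32 for phosphate starvation. Iron genes had -0.01, 0.06 and -0.08, root markers -0.11, -0.17 and 0.11, guard cell markers -0.09, 0.03 and -0.35, and vascular markers -0.07, 0.03 and 0.18; the sign of the iron and root medians in djc31 and of the guard cell and vascular medians in djc62 changed under other scalings. Within them, the cytosolic chaperone gene HSP90-2 rose in all 3 mutants (1521 ± 270 to 3212 ± 544, 3843 ± 213 and 4006 ± 313). The iron reductase gene FRO3 rose from 122.2 ± 45.2 to 577.4 ± 131, 457 ± 53.5 and 485.3 ± 23.2. The root aquaporin gene TIP2-3 had 55.7 ± 26.2 in wild type, 0 reads in djc31 (at least 44.6-fold lower), 2.11 ± 2.34 in djc62 and 0.496 ± 0.859 in the double mutant. Chloroplast-encoded transcripts made up 0.0426% ± 0.00388 of wild-type reads and 0.0356% ± 0.00659, 0.0256% ± 0.00691 and 0.031% ± 0.0014 of mutant reads (exact two-sided permutation p = 0.2, 0.1 and 0.1, where 0.1 is the smallest that 3 against 3 libraries can give).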

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

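The tests on depth, swapped labels, chromosome segments, clock genes near silent loci, and the level of wild type were chosen only after the results were seen; the test of clock genes outside the lists and the sample splits were written before.

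The 6236 non-additive genes stand out because the test of the difference between the djc31 or djc62 effect in 2 backgrounds passed. By the same contrast, 8 gene lists passed camera. Positive were flavonoid (adjusted p = 4.3e-08), cell division (0.00041), heat (0.0016), abscisic acid, auxin and glucosinolate genes (0.048 each), and negative were photosynthesis (4.8e-07) and jasmonate genes (1.2e-05). With an estimated correlation 0 of the 8 passed. The calls at 0.048 rose above the threshold under the replicate block and without wild type replicate 3, among other settings.

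Among single genes the contrast was 9.52 for LSU1, 7.95 for HA9, 7.38 for AT1G27570, 7.29 for AT1G12340 and 7.19 for AT3G60950 on the log2 scale. It was -11.03 for HSD2, -10.90 for AT3G47250, -10.30 for AT1G23960, -10.25 for AT3G42806 and -10.04 for HR4. For loci without reads in a genotype these are fitted values and no bounds.

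The loci silent in wild type are the pattern most in need of follow-up. Low depth is argued against by the reads themselves. At the lowest mutant level 156 to 4046 reads were due in wild type (median 409.5), where at most 3 were found. The choice of loci, with a value of at least 50 in each mutant library, made a high number due certain, so the median is no separate test. A swap of labels between wild type and mutants is argued against as well, because the lowest wild-type value of a target gene was 2.25 times the highest value in its own mutants. The loci lay nearer to each other than random expressed loci, with neighbours counted once (share of draws 6e-04). Chromosome segments of another strain in the wild-type plants would give this. The draws took expressed loci of any type, however, while 9 of the 34 silent loci were transposable element genes. Loci that share silencing could also lie near each other. The nearness therefore does not tell such segments from a heritable change in silencing shared by the mutants, which was not tested and stays open. Loci within 100 tested loci of a silent one were called somewhat more often than others against wild type (32% and 26.6% in djc31) but not in the double mutant against djc62 (19.6% and 19.9%), and where such segments would end was not measured.

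Clock genes shifted between wild type and the mutants, and another hour of harvest may account for it. In dawn and evening genes kept out of the lists, the evening genes lay 1.25 above the dawn genes on the log2 scale in the mean of the 3 mutants (permutation p = 0.0246 from 10000 random lists), with only 5 dawn and 3 evening genes tested. In the double mutant by itself the difference was 0.79 (permutation p = 0.0876), and single genes went against the shift (RVE7, of dawn, rose in djc31, and JMJ30, of evening, fell in the double mutant). Of the 3 evening genes, BOA had the largest rises in both single mutants (log2 1.78 and 1.66). Its counts were low (2.22 ± 2.32 in wild type, 8.35 ± 3.52 in djc31 and 7.36 ± 2.48 in djc62), and it passed in no mutant (limma adjusted p = 0.112, 0.139 and 0.441). The difference thus rests in part on a gene near the floor. The random lists also treat genes as independent, while the clock list had an estimated inter-gene correlation of 0.18. All 3 mutants were set against the same wild-type libraries as well, so the permutation p may be too small. List members away from silent loci gave 1.81, against 1.67 for all, so the shift does not rest on members near them. All 8 dawn genes and 4 of the 6 evening genes lay away from silent loci. With so little left out, the test could hardly have come out otherwise. An effect of the mutations on the clock itself predicts the same shift; it was not tested and stays open.

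The ratio of shares below cannot tell whether the non-additive changes arise from a wild-type level apart from all 3 mutants or from an interaction. Such a level does not by itself predict that effects reverse between 2 backgrounds, which share no library. The djc31 effect turned from rise to fall at 623 genes and from fall to rise at 579 (275 and 266 in independent lists). The djc62 effect did so at 614 and 730 (437 and 398). The effect kept its direction at 134 and 219 genes for djc31 and at 331 and 362 for djc62. For the genes that reversed, this argues against the wild-type level as the only source. Non-additive genes differed between the double and a single mutant 2.98 times as often as other genes (70.6% and 23.7%), above the bound of 1.5 set for the test. Both contrasts use the same double-mutant libraries, however, and giving each gene the wild-type deviation of a random other gene still gave a median ratio of 2.54 over 20 draws (2.48 to 2.58). The bound of 1.5 was therefore void. The real ratio lay above all draws, but the draws also removed any tie to the level and spread of a gene, so the excess excludes nothing; the test had been read as excluding the wild-type level until that ratio was computed.

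For each of the 5 pairwise comparisons, 1 of the 10 splits of the 6 libraries, the real one, gave as many genes, and the highest other split gave 0; 10 splits are too few for a share under 0.05. The real counts were 5489, 5326, 5839, 6255 and 3942. For the non-additive contrast 1 of 100 drawn splits, the real one, reached 6236, and the highest other gave 602. The drawn splits mix genotypes that differed at many genes. They therefore do not test the non-additive term by itself, and no conclusion on chance is drawn from them.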

How the results depend on the processing

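The edgeR test on recovered reads, TMM scaling and leaving out wild type or loci near silent ones were chosen after seeing the data. Of 8638 values for named genes under alternatives, 8509 stayed on their side of the threshold and 129 fell below it. Of those past it in either setting, 0 reversed. Most of these genes were named for large or clear changes in the same data, so few losses were likely from the start. All 190 values for target genes kept their call. With an absolute log2 change above 1 required, counts fell by construction to 1992, 1939, 1876, 1682, 1270 and 3458 in the order of the report. Leaving out each library in turn gave 4156 to 5613, 3838 to 6065, 4135 to 6617, 4073 to 6589, 2375 to 4739 and 4853 to 6732 genes; fewer samples in a genotype lower the power. The number of lists called ranged over 3 to 5, 6 to 7, 8 to 9, 6 to 10, 9 to 10 and 5 to 9. With an estimated correlation it was 0, 0, 0, 0, 1 and 0. With fry, which does not compare a list with other genes, it was 8, 12, 15, 16, 8 and 14, against 3, 7, 9, 7, 9 and 8 with camera. For the non-additive contrast 5 lists were called with pseudocount 0.1, and 5 without loci near silent ones; the cause was not tested. The replicate number as a replicate block gave 5204, 5048, 5509, 5974, 3613 and 5867 genes and 5 non-additive lists. Same-numbered libraries did not pair: residual correlations ran from -0.15 to 0.11, 1 of 18 pairs lay over 0.1, and 2 of 12 libraries correlated best with their own number. In the simulation, 39.1% of 23 genes changed 1.5-fold were recovered. Its spread was assumed and few genes were changed, so it does not measure the power in these data.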

Other observations

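Of the 2 hypotheses tested here, the test on DNA damage genes was chosen only after the result was seen: its list was written after GMI1 and NAC044 had stood out. The low-copper test was written before its result was seen, after CSD2 and CCS had stood out.

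Several genes of the DNA damage response were higher in the double mutant than in the single mutants. GMI1, induced by DNA breaks, had 551.8 ± 33.8 in the double mutant against 130.8 ± 19.6 in wild type, 66.7 ± 18.5 in djc31 and 51.3 ± 20 in djc62 (mean ± SD, n = 3). BRCA1 had 300.7 ± 24.3 against 188 ± 19.1, 146.7 ± 19.4 and 130.4 ± 23.1, and the cell cycle inhibitor gene SMR7 56.7 ± 4.2 against 9.8 ± 3.42, 19.5 ± 6.25 and 14.3 ± 11.1. NAC085 had 39.8 ± 5.46 in the double mutant and 0 reads in both single mutants.

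A candidate explanation is a DNA damage response in the double mutant. In a list of 17 damage genes without GMI1 and NAC044, 15 of 16 tested lay above the mean of the single mutants, with a median log2 difference of 0.83 (camera p = 0.000733 with an estimated correlation). Of the 16, 10 rose and 0 fell against djc31, 7 rose and 0 fell against djc62, and 8 rose and 0 fell against wild type. The median against wild type was 0.36, and some members had lower means in the single mutants than in wild type, such as PARP2 (213 ± 41.1 in wild type, 132.3 ± 67.5 in djc31, 90.6 ± 18 in djc62 and 247.2 ± 32.8 in the double mutant). Cell division genes, some of which are induced by damage too, were on balance higher in the same comparisons, and a higher share of dividing cells was not told from damage here.

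A low-copper response may lower CSD2 and CCS, which are repressed when copper is short. Of 11 genes of that response, 7 were tested in the double mutant against wild type; 4 rose and 1 fell, with a median log2 change of 0.45 (camera p = 0.338 with an estimated correlation). FSD1 rose from 16430 ± 1230 to 22470 ± 942 and CITF1 from 0.536 ± 0.928 to 12.5 ± 0.795, while COPT2 fell from 356.4 ± 71.3 to 114.9 ± 14.4. FSD1 was as high in djc31 (22840 ± 1700) and djc62 (21660 ± 2380), and did not pass in the double mutant against either, where CSD2 fell (log2 change -2.01 and -1.67). Of genes repressed under low copper, CSD1 fell from 4971 ± 558 to 2474 ± 230, which goes with the explanation, and UCLA rose from 77.1 ± 12.7 to 154.2 ± 5.21, which goes against it, while LAC2 and LAC4 did not pass (adjusted p = 0.666 and 0.983). The prediction written beforehand took p at or above 0.05 as evidence against the explanation, and the result meets it. After the result was seen that bound was judged wrong, because a p that misses the threshold bounds no value and the tested genes went both ways, so the hypothesis is neither borne out nor excluded.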
